A study of Homo sapiens with 4 samples.

How the data were processed

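RNA of 4 samples of RUES2 cells at day 5 of cardiac differentiation was measured on single-colour Illumina arrays with biotin-labelled cRNA, per the labels. The deposited scanner table gives, per the file headers, a signal intensity for each of 47322 probes on each array and a detection p-value beside it. These deposited intensity values are linear and not normalized, as their differing medians show. The deposited series matrix holds log2 values of the same arrays. Set against the scanner signals, it lay within 0.158 of a quantile normalization of log2 signal, with a median difference of -0.0363, and its column medians were 7.02 on every array. Its exact normalization is not given in the sources used here. The tools lumi and limma 3.12.3 are named per the submitters' processing notes, with no role stated.

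Groups were taken from the labels: 2 arrays with control shRNA and 2 with TMEM88 shRNA, of which 1 carried hairpin 691 and 1 hairpin 94. The sample titles hold a different replicate-like code for each array, whose meaning is not given. With no code shared between groups, no pairing was used. The labels name no slide or batch.

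Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, and negative control values were inferred from the detection p-values. Probe names came from the platform annotation: 30113 probes had 1 gene symbol, 8 had several and 17201 had none, and the symbols of 30074 probes matched the gene table of assembly GCF_000001405.40 (GRCh38.p14), used for names and neighbours only. Of 20046 named genes on the array, 10377 were tested, each by the probe with the highest mean among those with a detection p under 0.01 on at least 2 of 4 arrays. Groups were compared with lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 2 residual degrees of freedom and 4.84 prior ones. Single hairpins were tested in a fit with 3 groups and 1 residual degree of freedom, in which a lone array is assumed to vary like the controls. Differences are TMEM88 shRNA minus control, with standard errors.

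Gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. There were 29 lists with 592 genes, of which 27 had at least 5 tested members and entered limma's camera with a preset correlation of 0.01, adjusted over the lists. The named genes are TMEM88, the 10 largest rises and falls among called genes with non-overlapping arrays, up to 3 called members of each list (or the 2 brightest, as values, where none was called), and the 5 largest differences in each direction between hairpins. Genes with LOC or open reading frame names were skipped in the rankings. A gene undetected on both arrays of a group has a bound there. Unchanged groups and the controls they share were simulated in 100 draws, each gene drawn independently with the spread of its 2 real controls.

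The steps were tested on simulated data with 10377 genes, 200 of them changed. Of changes of 1, 2 and 3 on the log2 scale, the comparison of TMEM88 shRNA with control recovered 6.5%, 82.8% and 97.8%, with 4.6% false calls. For shRNA 691 alone the shares were 1.6%, 45.4% and 94.8%, with 9.1% false calls, and for shRNA 94 alone 1.5%, 47.2% and 94.7%, with 10.8% false calls. The false share for a single hairpin thus lay above the nominal level. Simulated lists of 12 genes shifted by 1 were found by camera in 100% of cases with the preset correlation and in 0% with an estimated one. The simulated genes were independent of each other, so this does not judge the preset for lists of correlated genes.

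Alternatives covered background correction, normalization, the deposited log2 matrix, the detection filter, the probes per gene, the variance model, the threshold, the set test and leaving out each array. Figures were drawn with matplotlib 3.10.9.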

Results

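Gene expression was measured on 4 Illumina bead arrays in RUES2 cells, an established human embryonic stem cell line, at day 5 of directed cardiac differentiation, the stage of cardiovascular progenitors. Undifferentiated cells had been transduced with lentivirus carrying a short hairpin RNA (shRNA), selected with puromycin and then differentiated. Of the 4 arrays, 2 came from cells with a control shRNA (controls 1 and 2) and 2 from cells with an shRNA against TMEM88, a membrane protein gene linked to Wnt signalling. The TMEM88 group held 1 array for each of 2 hairpins, named 691 and 94, so its spread contains the difference between hairpins. Each array carried 47322 probes, of which 15618 and 15300 were detected in the controls, 16516 with shRNA 691 and 16240 with shRNA 94. The median signals were 130.9, 132.2, 135.7 and 132.5. Nothing in the labels says that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

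The first comparison asked how far each hairpin lowered its target. TMEM88 had a probe that was detected on all 4 arrays, with signals of 2292.8 and 2987 in the controls, 360.7 with shRNA 691 and 1329.7 with shRNA 94. After normalization TMEM88 stood at 9.62% of the control geometric mean with shRNA 691 and at 52.9% with shRNA 94, against 85.4% and 117% in the controls themselves. Over both hairpins the TMEM88 log2 difference was -2.15 ± 0.71 (SE, n = 2 per group), with a limma adjusted p of 0.187, which did not pass the threshold of 0.05. Fitted separately against the controls, TMEM88 fell with shRNA 691 (log2 difference -3.38, limma adjusted p = 0.0146), while shRNA 94 gave -0.92 (limma adjusted p = 0.591). The difference for TMEM88 between the hairpins was -2.46 and did not pass either (limma adjusted p = 1).

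The main comparison set both TMEM88 hairpins against both controls. MESP1, EOMES and SP5 were among the 10 largest rises, and HBE1 and SMYD1 among the 10 largest falls. MESP1, a transcription factor of nascent cardiac mesoderm, rose by a log2 difference of 3.68 ± 0.42 (SE, n = 2 per group), and EOMES, a T-box factor of the primitive streak, rose by 3.33 ± 0.46. HAND2, a transcription factor of heart development, was lower by a log2 difference of -3.74 ± 0.25, and the atrial myosin light chain gene MYL7 by -2.58 ± 0.29. SMYD1, a methyltransferase gene of heart and skeletal muscle, was detected on both control arrays and on neither TMEM88 shRNA array, a fall of at least 12.6-fold.

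In limma, 205 of 10377 tested genes changed, 99 higher and 106 lower, with a median change of 4.12-fold among them. All 205 differed at least 2-fold, but smaller changes were rarely within reach of the test. It recovered 6.5% of simulated log2 changes of 1 and 82.8% of those of 2. The 2-fold minimum and the median thus reflect what could be called. At an unadjusted p under 0.05 there were 1903 genes, where chance alone gives 518.85. The arrays of the groups did not overlap for 5207 genes (50.2%), against 33.3% by chance. The count of 205 moved by over 1.5 times without any of the arrays. Each such fit leaves 1 array in a group and takes its residual spread from the other group's pair alone. That pair's SD over genes was 0.359 for the TMEM88 shRNA arrays and 0.562 for the controls. Without shRNA 691 or 94 the fit is the test of the other hairpin alone, so it is no separate check. With no detection filter the count was 19.

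The largest rise was that of CYP26A1, which encodes an enzyme that breaks down retinoic acid (log2 difference 4.64 ± 0.72, limma adjusted p = 0.0293). Its controls lay 2.54 apart on the log2 scale, and both were below both TMEM88 shRNA arrays. The cystatin gene CST1 rose by 4.37 ± 0.53 and the Wnt-responsive transcription factor gene SP5 by 3.29 ± 0.32 (limma adjusted p = 0.0148 and 0.0068). SHISA3 rose by 3.26 ± 0.33 and the growth factor gene NRG1 by 3.13 ± 0.31. The neural and early embryonic transcription factor genes ZIC2 and OTX1 rose by 3.43 ± 0.50 and 3.18 ± 0.41. LOX, encoding lysyl oxidase, was undetected on both control arrays and was at least 6.55-fold higher with the TMEM88 hairpins (limma adjusted p = 0.00571). Such bounds set the brighter group's mean against, per array, the higher of the lowest detected signal and the probe's own signal.

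Among the falls, the embryonic globin gene HBE1 was at least 24.3-fold lower (limma adjusted p = 0.00113), from 2 control arrays where it was detected to 2 TMEM88 shRNA arrays where it was not. The dynein heavy chain gene DNAH2 was lower by a log2 difference of -4.76 ± 0.30, and the imprinted long noncoding RNA H19 by -4.51 ± 0.40 (limma adjusted p = 0.00406 and 0.00571). TXNIP, which encodes a thioredoxin-binding protein, had a log2 difference of -4.09 ± 0.40. RGS4, a regulator of G-protein signalling, had -4.13 ± 0.60 and the zinc transporter gene SLC30A3 had -4.02 ± 0.45. The homeobox gene HOXB2 had a log2 difference of -4.01 ± 0.36, and HAPLN1, which encodes a link protein of the extracellular matrix, had -3.96 ± 0.28. The second probe of HAPLN1 gave -2.78. DGKI, a diacylglycerol kinase gene, was at least 7.63-fold lower. Among genes with a printed difference, DNAH2, HAND2, MYH6 and CYCS were detected on 1 of the 2 TMEM88 shRNA arrays. OTX1, OTX2 and SOX2 were detected on 1 of the 2 control arrays. The size of these differences is thus uncertain. KCNJ2 and TM4SF1 were detected on 1 array of each group and WNT3A on no control array.

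**Figure D1:**
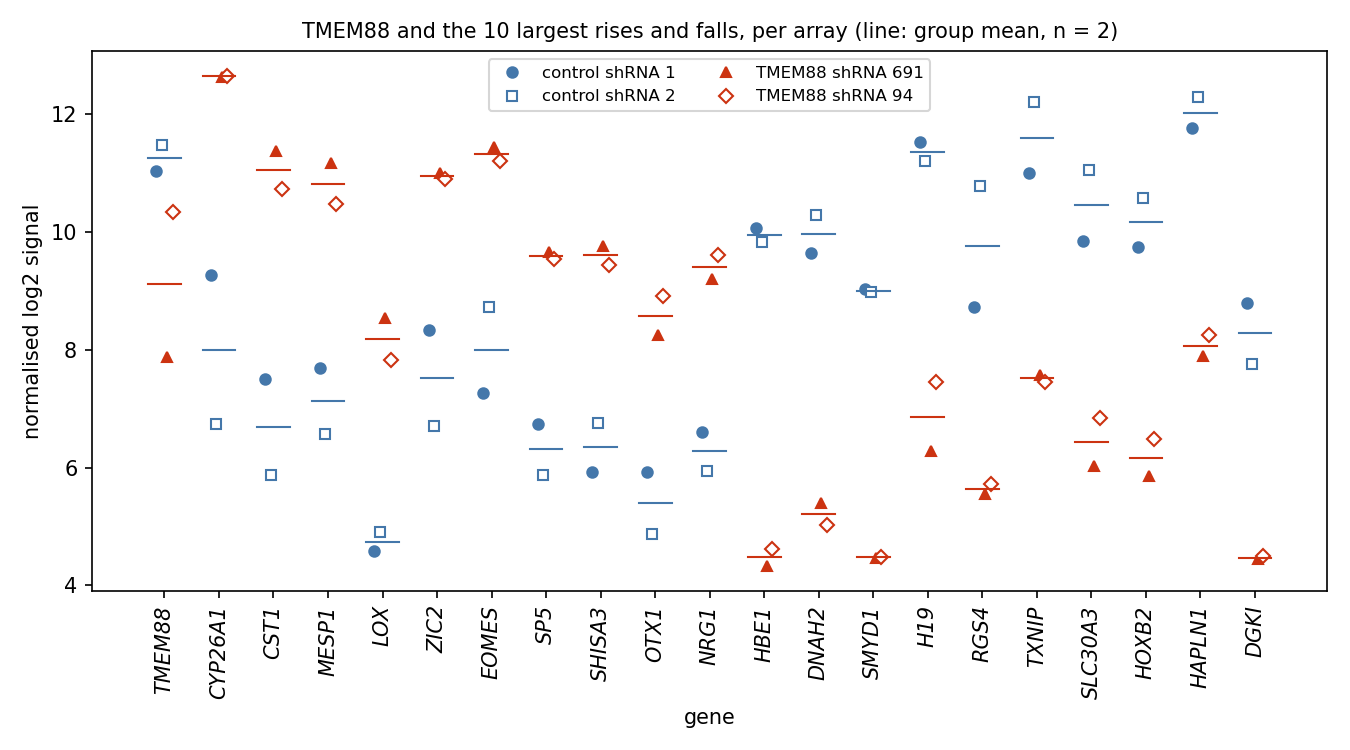
Normalised log2 signal (vertical axis) of TMEM88 and of the 10 genes with the largest rise and the 10 with the largest fall (horizontal axis), with a point for each of the 4 arrays and a line at each group mean (n = 2). For HBE1 the controls lie at 10.08 and 9.83 and the TMEM88 shRNA arrays at 4.32 and 4.62, while for TMEM88 the shRNA arrays lie apart, at 7.88 and 10.34.

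The gene lists, fixed before the data were examined, describe the same comparison by lineage. Of 10 tested genes of the primitive streak and mesendoderm, 4 rose and none fell, among them MESP1, EOMES and SP5, and 9 had a positive log2 difference. Adjusted over the list alone, 7 rose. GSC and WNT3A, detected on no control array, passed the filter only through the group where they were high. The counts and tests of this list include them. The median of the list was 1.79 (limma camera adjusted p = 1.6e-06, and adjusted p = 0.322 with an estimated correlation). The estimated setting found 0% of simulated shifted lists, so its values here and below do not count against a list. Of 6 tested genes of paraxial mesoderm, the tissue that forms somites, 3 rose: the Notch ligand gene DLL3 by 1.60 ± 0.27, the Notch modifier gene LFNG by 1.45 ± 0.24 and the forkhead gene FOXC2 by 1.37 ± 0.23. Adjusted over the list alone, 5 of these 6 rose. TCF15, detected on no control array, passed the filter only through the group where it was high, and DLL1 was detected on 1 control array. The counts and tests of this list include both. The paraxial median was 1.41 (limma camera adjusted p = 2.9e-05, and adjusted p = 0.322 with an estimated correlation). DLL3 and FOXC2 each had a second probe with a smaller difference, 0.85 and 0.59.

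Of 13 cardiac progenitor transcription factors, 2 fell, HAND2 as above and MEF2C, which was at least 3.14-fold lower (limma adjusted p = 0.00571), and none rose. Adjusted over the list alone, 5 fell. The list was mixed too: 4 of its genes had a positive difference, among them NKX2-5 (0.97 ± 0.42), HAND1 (0.71 ± 0.50) and ISL1 (0.03 ± 0.26). The list median was -0.38 (limma camera adjusted p = 0.00139, and adjusted p = 0.322 with an estimated correlation). Of 12 contractile and hormone genes of cardiomyocytes, 3 fell, with log2 differences of -3.38 ± 0.24 for MYL4, -2.58 ± 0.29 for MYL7 and -2.48 ± 0.26 for MYH6. The second probe of MYL4 gave -1.09. Adjusted over the list alone, 6 fell and 2 rose, so the list was mixed, with a median of -0.67 (limma camera adjusted p = 0.0211, and adjusted p = 0.376 with an estimated correlation). Of 7 smooth muscle genes ACTA2 alone fell (-3.13 ± 0.43), and the list did not pass (limma camera adjusted p = 0.203). Of 10 fibroblast and epicardial genes 2 fell, LUM, at least 3.89-fold lower, and PDGFRA, with a log2 difference of -1.39 ± 0.23. Adjusted over the list alone, 5 of these 10 fell. That list had a median of -0.80 (limma camera adjusted p = 0.00474, and adjusted p = 0.322 with an estimated correlation).

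Lists of other lineages also moved. Of 11 endoderm and liver genes, CXCR4, a chemokine receptor gene also active in definitive endoderm, rose by 2.05 ± 0.28. Adjusted over the list alone, 8 endoderm genes rose. CER1 and TTR, detected on no control array, passed the filter only through the group where they were high. HHEX and APOA2 were detected on 1 control array. The endoderm median was 1.14 (limma camera adjusted p = 5.8e-06, and adjusted p = 0.322 with an estimated correlation). None of 10 endothelial genes passed over all genes and 5 rose adjusted over the list alone. VWF stood at 1.88 ± 0.34 (limma adjusted p = 0.0502) and SOX18 at 1.32 ± 0.28 (limma adjusted p = 0.0707). The endothelial median was 0.78 (limma camera adjusted p = 0.00139, and adjusted p = 0.322 with an estimated correlation). All 11 tested pluripotency genes had a positive difference and none passed, over all genes or adjusted over the list alone. LIN28A stood at 0.28 ± 0.26 and DPPA4 at 0.58 ± 0.24. The largest differences in this list were those of POU5F1 (1.35 ± 0.61, with the controls at 6.81 and 8.88) and SOX2 (1.22 ± 0.44). The pluripotency median was 0.58 (limma camera adjusted p = 0.00139, and adjusted p = 0.465 with an estimated correlation). Of 4 measured neural ectoderm genes, too few for a list test, ZIC2 and OTX2 rose, OTX2 by 2.50 ± 0.44, with its 3 detected probes between 1.41 and 2.50. Control 1 exceeded control 2 by a median of 1.41 over these 4 genes. Of 4 measured HOX genes HOXB2 fell, and of 5 blood genes HBE1 fell (limma camera adjusted p = 0.284). None of 6 trophoblast and amnion genes passed (GATA3 0.65 ± 0.25, TFAP2C -0.38 ± 0.60, limma camera adjusted p = 0.59), and control 1 lay below control 2 by a median of -1.02 there.

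None of 16 epithelial genes passed over all genes and 5 rose adjusted over the list alone. The keratin genes KRT19 and KRT8 stood at 0.15 ± 0.22 and 0.32 ± 0.28. The epithelial median was 0.68 (limma camera adjusted p = 2.6e-04, and adjusted p = 0.445 with an estimated correlation). Of 10 genes of mesenchymal transition, VIM fell by 2.03 ± 0.25 and SNAI2 rose by 1.43 ± 0.25, while 4 rose and 2 fell adjusted over the list alone (limma camera adjusted p = 0.884). Among signalling lists, 3 of 23 Wnt pathway components passed. The receptor genes FZD7 and FZD2 rose by 1.96 ± 0.28 and 1.56 ± 0.25, and the ligand gene WNT5A fell by 1.78 ± 0.24. The second probe of FZD7 gave 0.43. The median of the Wnt components was 0.39 (limma camera adjusted p = 0.029, and adjusted p = 0.581 with an estimated correlation), and 7 rose and 3 fell adjusted over the list alone. Of 13 Wnt target genes SP5 alone rose (limma camera adjusted p = 0.528). Of 12 Notch genes DLL3 and LFNG rose and HEY1, a Notch target also active in the heart, fell by 2.81 ± 0.42. The Notch median was 0.64 (limma camera adjusted p = 0.00236, and adjusted p = 0.445 with an estimated correlation). None of 15 BMP genes passed (ID3 1.13 ± 0.30, BAMBI -1.20 ± 0.25, limma camera adjusted p = 0.227), while 5 rose and 2 fell adjusted over the list alone.

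Of the metabolic lists, 16 hypoxia and glycolysis genes had a median of 0.72 with none passing singly (ENO1 0.07 ± 0.23, SLC2A3 0.22 ± 0.25). Their limma camera adjusted p was 5.6e-04, and adjusted p = 0.322 with an estimated correlation. All 12 cholesterol synthesis genes had a negative difference, and SC5D fell by 2.48 ± 0.27. Their median was -0.48 (limma camera adjusted p = 7.2e-04, and adjusted p = 0.445 with an estimated correlation). CYCS, encoding cytochrome c, fell by 1.97 ± 0.29 among 26 genes of oxidative phosphorylation (limma camera adjusted p = 0.718), and TP53I3 fell by 1.42 ± 0.22 among 13 p53 targets (limma camera adjusted p = 0.523). No gene passed among 29 cell cycle genes (MCM7 -0.28 ± 0.22, CDC20 -0.10 ± 0.27), 35 ribosomal protein genes (RPS12 0.06 ± 0.22, RPS27 0.01 ± 0.22) or 10 genes of the RNA interference machinery (TARBP2 -0.21 ± 0.24, TNRC6B -0.12 ± 0.25). Their limma camera adjusted p-values were 0.884, 0.764 and 0.339. Nor did any pass among 14 genes of unfolded protein and amino acid stress (PHGDH 0.10 ± 0.23, ATF4 -0.34 ± 0.30, limma camera adjusted p = 0.412), 10 immediate early genes (CCN2 0.82 ± 0.53, DUSP6 -0.52 ± 0.22) or 10 interferon genes (BST2 1.04 ± 0.69, HERC5 0.67 ± 0.23). The last lists both had a limma camera adjusted p of 0.97. For interferon genes the median (0.06) and mean were positive where camera gave a downward direction, and for immediate early genes the mean alone was positive.

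Adjusted over the list alone, the remaining counts were 4 risen and 1 fallen Notch genes, 2 risen and 1 fallen Wnt targets, 2 risen and 1 fallen neural genes, and 1 risen and 1 fallen blood genes. On the same terms 2 HOX genes, 2 cholesterol genes, 1 smooth muscle gene, 1 trophoblast gene, 1 p53 target and 1 gene of oxidative phosphorylation fell and 1 hypoxia gene rose. None did among cell cycle, ribosomal, RNA interference, protein and amino acid stress, immediate early and interferon genes. Calls of single genes over all genes moved when a control was left out. Such a fit takes its residual spread from the TMEM88 shRNA arrays alone, so more calls need not reflect the control itself. Without control 1 and without control 2 there were 6 and 4 risen endoderm genes, 4 and 6 epithelial, 3 and 3 endothelial, 6 and 2 hypoxia and 2 and 1 pluripotency genes, and 6 and 0 risen and 3 and 2 fallen BMP genes. Wnt targets had 2 and 3 rises and 4 and 1 falls on these terms, with the controls a median of -0.63 apart. Without control 1, 3 trophoblast genes and 1 RNA interference gene fell, 2 cell cycle genes rose, and 2 immediate early genes rose and 2 fell. Without control 2, 1 cell cycle gene fell. Ribosomal and interferon genes each had 1 fall without control 1 and 1 rise without control 2, and the protein and amino acid stress list had 1 rise without either and 1 fall without control 1. Of the 27 lists tested, 13 passed with camera's preset correlation, 9 upward and 4 downward. With an estimated correlation none passed. That setting found 0% of shifted lists in simulated data of this size, whose genes were independent. The estimate was 0.31 for pluripotency, 0.24 for cholesterol synthesis and 0.19 for streak genes, above the preset of 0.01. It was below the preset for fibroblast and epicardial (-0.11), endoderm (-0.10) and paraxial genes (-0.08). These lists did not pass with the estimate either (limma camera adjusted p = 0.322). Not passing with an estimated correlation thus does not count against a list. The simulation does not settle whether the preset suits these lists. The rotation test fry called 3 lists, paraxial mesoderm and endoderm upward and cardiac transcription factors downward, each at a limma fry adjusted p of 0.0461. The paraxial and endoderm lists hold genes detected on no control array, as given above.

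**Figure D2:**
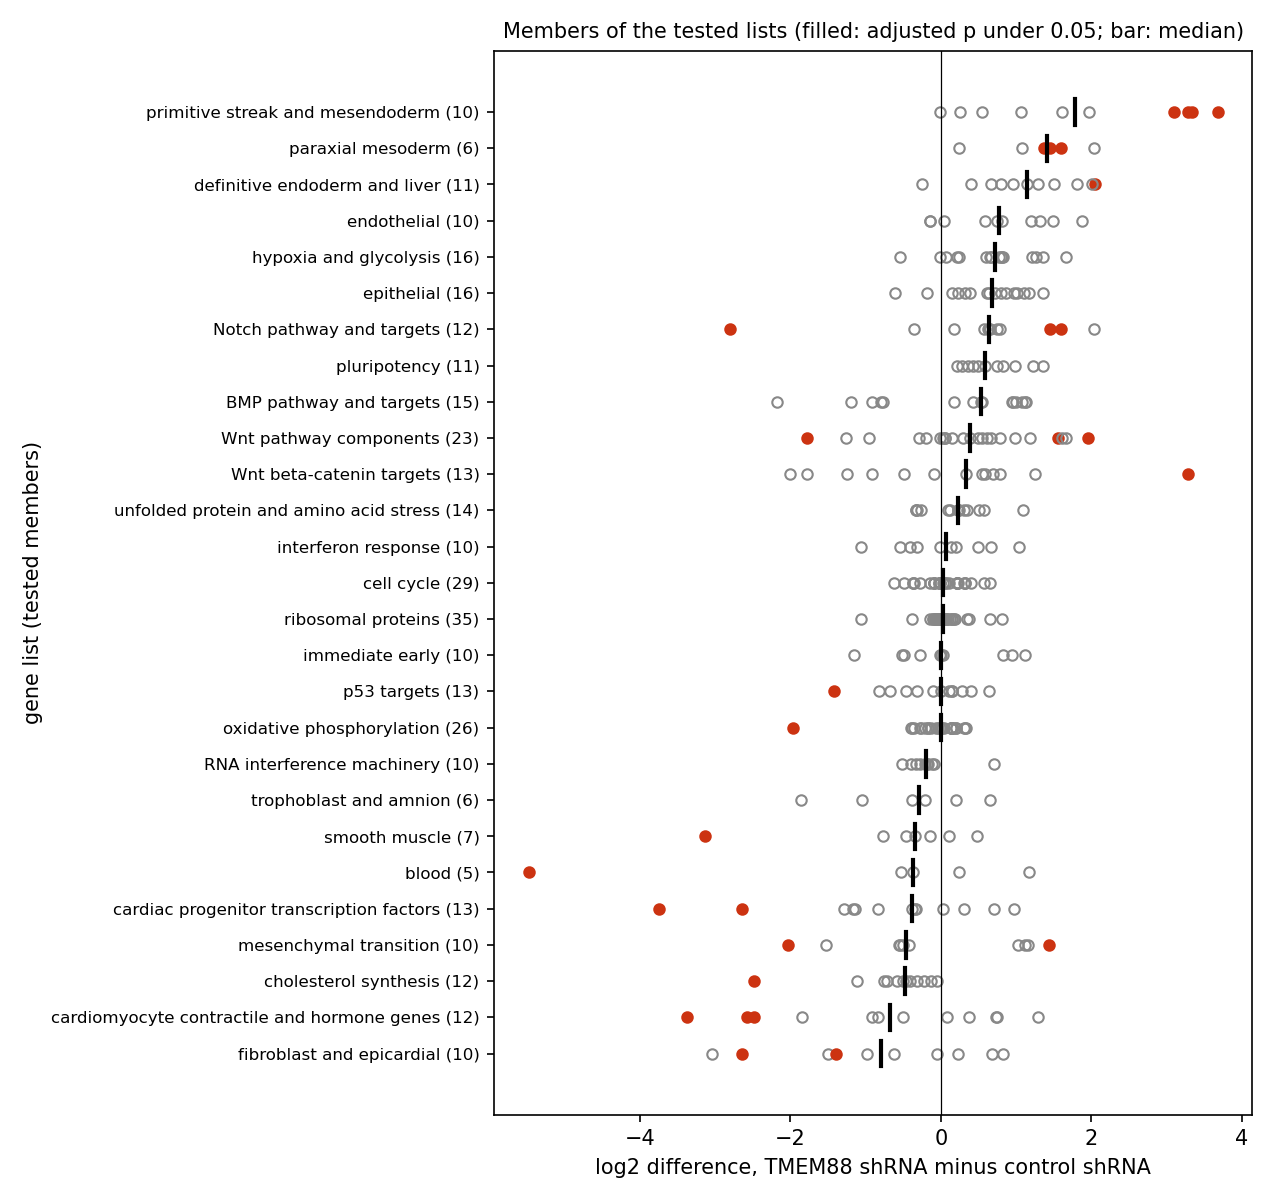
Log2 difference of TMEM88 shRNA minus control shRNA (horizontal axis) for every tested member of the 27 tested lists (vertical axis, with the number of tested members), filled where the gene passed and with a bar at the list median. The medians run from -0.80 for fibroblast and epicardial genes to 1.79 for the primitive streak list.

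The last comparison asked whether the 2 hairpins gave alike changes. Against the controls, shRNA 691 changed 90 genes in limma (35 higher, 55 lower) and shRNA 94 changed 50 (15 higher, 35 lower). Of these, 13 higher and 31 lower genes were shared, and none changed in opposite directions. Independent lists would share 0.0506 and 0.186. Unchanged groups simulated together with simulated shared controls gave 0 calls and 0 shared calls on average. Their top-ranked lists of the same sizes shared a mean of 4.01 higher and 9.36 lower genes (at most 8 and 15 in 100 draws). The counts of 90 and 50 became 19 and 5 with no background correction, 46 and 26 with the deposited matrix, 32 and 3 when detected on all arrays and 0 and 0 with no detection filter. HBE1, SMYD1, HOXB2 and HAND2 passed with either hairpin alone, while EOMES passed with shRNA 691 (log2 difference 3.46, limma adjusted p = 0.0394) and stood at 3.21 with shRNA 94 (limma adjusted p = 0.0613).

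Across all 10377 genes, which are not independent replicates, the log2 differences of the hairpins had a covariance of 0.329 and a correlation of 0.836. They had the same sign for 78.2% of genes. Unchanged groups simulated together with simulated shared controls gave a mean covariance of 0.0789, a correlation of 0.332 and 60.8% of genes with the same sign. The real controls set only each gene's spread there, and genes were drawn independently. The covariance exceeded the simulated mean by 0.25. With no background correction it was 0.137 against a simulated 0.0321, with the deposited matrix 0.138 against 0.0323 and with no detection filter 0.186 against 0.0532. With a different control for each hairpin, a choice made after seeing the data, the covariance was 0.244 or 0.256. The correlation was then 0.518 or 0.560 and the share with the same sign 61.8% or 64.4%. No control is shared there, so the simulated values above, made with shared controls, are no yardstick for these. Unchanged arrays with noise independent between arrays would have no covariance there on average. A shared control is thus argued against as the whole source of the covariance, though the spread around that average was not simulated. The controls were too few to split into groups of 2, so part of the excess in shared calls may come from the shared controls.

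No gene differed between shRNA 691 and shRNA 94 in limma, and 98 genes reached an unadjusted p under 0.05, below the 518.85 that chance gives. This sets 1 array against 1 with the spread of the controls, which was the larger spread, and TMEM88 itself did not pass, so the 0 does not show that the hairpins acted alike. The largest values in favour of shRNA 691 were those of LCN15 (2.03), GOLGA8B (1.80), SNORA61 (1.72), WNT3A (1.68) and KAT2A (1.59). The largest in favour of shRNA 94, as 691 minus 94, were those of TMEM88 (-2.46), DDIT4L (-1.98), SPX (-1.89), KCNJ2 (-1.80) and TM4SF1 (-1.66). The SD over genes of the log2 difference was 0.359 between the TMEM88 shRNA arrays and 0.562 between the controls. Across the groups it lay between 0.612 and 0.748.

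**Figure D3:**
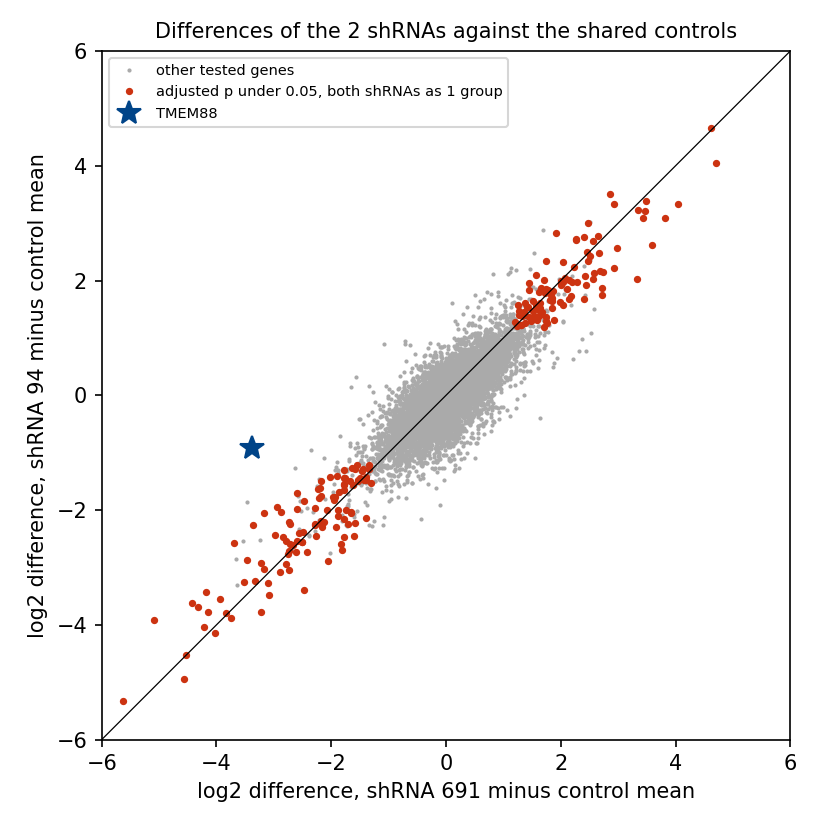
Log2 difference against the mean of the shared controls for shRNA 691 (horizontal axis) and shRNA 94 (vertical axis), with a point per tested gene, the 205 called genes in red, TMEM88 as a star and the line of equal differences. TMEM88 lies off that line, at -3.38 and -0.92.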

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

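Camera, fry and limma results of tested genes, for the real groups or single hairpins, came from planned comparisons. All other tests in this part were chosen after the result was seen or after values that bear on it were known. Among named genes, 5 had a TMEM88 hairpin on either side of both controls. The difference of shRNA 691 minus shRNA 94 was 2.03 for LCN15, 1.59 for KAT2A, -0.52 for CDC20, -1.98 for DDIT4L and -1.66 for TM4SF1. Each rests on 1 array per hairpin, and none passed in limma (smallest adjusted p = 1 over all genes). Outside the named genes, 3216 of 17209 probes with no single gene symbol were detected, and 21 of them differed between TMEM88 shRNA and control (10 higher, 11 lower in limma).

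Of 10 primitive streak genes 4 rose, and of 12 contractile genes 3 fell. The contractile list was mixed: 5 of its 12 genes had a positive difference, and 2 rose adjusted over the list alone. The list calls came from camera with its preset correlation. An estimated one gave limma camera adjusted p = 0.322 for streak and 0.376 for contractile genes. That setting found 0% of shifted lists in simulation, where genes were independent, so these values do not count against either list. The estimate was 0.19 for streak and -0.03 for contractile genes, so the preset of 0.01 may be too small for the streak list. With shRNA 94 alone LEFTY2, EOMES and MYH6 did not pass (limma adjusted p = 0.158, 0.0613 and 0.0567). Normalization between arrays as the whole cause is argued against: before any normalization the streak mean exceeded the contractile mean by 1.96 (permutation p = 4.7e-04 over genes, taken as independent). After processing that gap was 2.66, so part of its size depends on the processing. Remaining undifferentiated cells stay open. The streak list rose more than the pluripotency list by a mean of 1.20 over all members (exact permutation p = 0.0137 over genes), but the highly expressed pluripotency genes could hide a small share of such cells. With members limited to a control level under log2 11, 10 and 9 the difference was 1.37, 1.33 and 1.27 (exact permutation p = 0.00551, 0.0179 and 0.0424). Under log2 8 and 7 it was 1.18 and 0.846 (exact permutation p = 0.0844 and 0.343), with 9 against 5 and 4 against 3 members, so the limit is not shown to remove the difference and the dimmest members are too few to decide. The streak genes GSC and WNT3A and the pluripotency gene USP44 were detected on no control array. They passed the filter only through the group where they were high, and these permutation tests include them. A general delay of differentiation, the biological explanation, cannot be told apart from a change of lineage with a single day. The endothelial list, with 10 of 29 members tested, had a median of 0.778 and 8 of 10 genes positive. Adjusted over the list alone, 5 rose and 0 fell (exact sign-flip p = 0.0137 over genes). ECSCR and CD34 were detected on both TMEM88 shRNA arrays and on no control array. They passed the filter only through the group where they were high, so the sign-flip p does not decide. The list had a limma fry adjusted p of 0.0804. Its 5 genes detected on all arrays had a median of 0.741.

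With 4 arrays there are 3 splits into groups of 2, too few for a share under 0.05. The real split gave 205 genes and the highest of the others gave 0, and 1 split, the real one, reached 205.

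The control arrays differed more from each other than the TMEM88 hairpins did. Noise that is independent between genes is argued against, since 9 of 27 lists had a median difference between the controls outside the central 95% of 10000 random lists matched on mean level. Cell cycle genes were higher in control 1 for 26 of 29 members (median 0.44), and immediate early genes had a median of -1.02. RNA of the TMEM88 shRNA samples mixed into control 1, with only noise independent between genes besides, is argued against. At shares from 0% to 100% in steps of 10%, between 8 and 18 of the 27 lists had a median of control 1 minus the mixture outside the central 95% of 1000 matched random lists. Random lists hold unrelated genes, so variation that list members share between samples could also give such counts. The same count was not made between the hairpins. A mixture together with another difference stays open. Over all genes control 1 lay on the side of the TMEM88 shRNA arrays (slope of the control difference on the shRNA difference 0.232, 95% bootstrap interval over genes 0.206 to 0.256), which a noisier control 2 could also give. The best share, 49%, left an SD of 0.462 between control 1 and the mixture, against 0.359 between the hairpins, a comparison that rests on single arrays. A difference in the state of the cultures stays open. The titles of the controls differ in a code whose meaning is not given. No biological explanation was tested, since the labels give none within the controls.

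On 1 array per hairpin the TMEM88 signal was higher with hairpin 94 than with hairpin 691. This difference did not pass (limma adjusted p = 1). Over all tested genes the changes were of similar size, but not within every list. The streak median was 2.26 with shRNA 691 and 1.35 with shRNA 94, and the pluripotency median 0.74 and 0.41. Other lists went the other way, such as contractile genes with medians of -0.46 and -0.80. Whether these list values follow the TMEM88 level was not tested. If the TMEM88 levels are as measured, changes in proportion to its loss on the log2 scale are argued against: the slope of shRNA 94 on shRNA 691 over all genes was 0.965 (95% bootstrap interval over genes 0.945 to 0.985), after removing the covariance of the shared controls. For TMEM88 the same ratio was 0.219 or 0.318, depending on the control. A saturating response to TMEM88, an effect common to both viruses and a TMEM88 level misjudged on 1 array stay open and were not tested, and no biological explanation was tested.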

How the results depend on the processing

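Over 102 named genes and lists, 1199 values under other settings stayed on their side of the threshold, 23 passed newly, 86 no longer passed and 0 calls reversed. The cause of the moves below was not tested unless stated. The TMEM88 difference ranged from -3.38 to -0.92 when an array was left out, and it passed only without shRNA 94 (limma adjusted p = 0.0146). The main count of 205 became 19 with no detection filter, 309 with a trended and robust variance and 448 at an adjusted p under 0.1, and ranged from 50 to 1453 when an array was left out (50 and 90 without shRNA 691 and 94, 548 and 1453 without control 2 and 1). All 19 genes without the filter were among the 205, and 31.6% of them were higher against 48.3%. Detected on all 4 arrays, 128 of 128 called genes still tested remained called. The count for shRNA 691 (90) became 19 with no background correction, 46 with the deposited matrix, 0 with no filter and 32 when detected on all arrays. For shRNA 94 (50) it became 5, 26, 0 and 3 under these settings, 79 with median scaling and 103 with the trended variance. The higher share for shRNA 691 fell from 38.9% to 21.1% with no background correction, and for shRNA 94 from 30% to 0%. List calls fell from 13 to 0 with an estimated correlation and to 3 with fry, and ranged from 12 to 13 when an array was left out. They were 11 with no filter and 9 when detected on all arrays, where 9 of 12 lists still tested remained called. The covariance (0.329) was 0.137 with no background correction, 0.188 with normexp, 0.138 with the deposited matrix, 0.186 with no filter, 0.265 when detected on all arrays and 0.307 at a detection p under 0.05. It was 0.244 and 0.256 with a control per hairpin, chosen after seeing the data, and 0.324 to 0.492 when a control was left out. No gene differed between hairpins under any setting run. No slide was given, so a slide block was not run, and single-hairpin counts without a control had no residual degrees of freedom. Between 32.3% and 34.9% of probes were detected per array, which limits what can be said of dim genes.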

Other observations

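The gene groups in this part were chosen after values were seen, so the tests on them are not independent of those values. Genes of retinoic acid metabolism moved in both directions. CYP26A1, which degrades retinoic acid, rose, and RDH10, which makes its precursor retinaldehyde, fell by 2.57 ± 0.31 on the log2 scale (limma adjusted p = 0.0148). ALDH1A2, the synthesis enzyme of the early embryo, stood at -3.04 ± 0.63 (limma adjusted p = 0.0657) and the receptor gene RARB at -1.44 ± 0.31 (limma adjusted p = 0.077). Of 11 tested genes, 1 rose and 4 fell adjusted over the list alone. The list did not pass with camera (limma camera adjusted p = 0.292) and passed downward with fry (limma fry adjusted p = 0.0386 over the 3 lists chosen after seeing the data).

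Of 13 TALE homeobox genes, MEIS1, MEIS2 and PBX3, cofactors of HOX proteins, fell, with log2 differences of -2.71 ± 0.27, -3.11 ± 0.24 and -1.96 ± 0.27 (limma adjusted p = 0.0068, 0.00525 and 0.0206). The list median was 0.22 and its mean -0.27, and adjusted over the list alone 3 rose and 3 fell. The list did not pass with camera (limma camera adjusted p = 0.88) and passed downward with fry (limma fry adjusted p = 0.00127). Of 14 imprinted genes H19 fell and DLK1 rose by 2.06 ± 0.27 (limma adjusted p = 0.0187). IGF2, the neighbour of H19, detected on 1 TMEM88 shRNA array, stood at -0.85 ± 0.25 (limma adjusted p = 0.143), and the list did not pass (limma camera adjusted p = 0.88, limma fry adjusted p = 0.573).

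Of 7 tested coding neighbours of TMEM88, within 5 genes on either side in the gene order of GRCh38.p14, 2 fell, DNAH2 with a log2 difference of -4.76 ± 0.30 and CYB5D1 with -2.44 ± 0.36 (limma adjusted p = 0.00406 and 0.0255). Of the genes next to TMEM88, NAA38 stood at 0.21 ± 0.23, and KDM6B, detected on no TMEM88 shRNA array, was at least 1.41-fold lower (limma adjusted p = 0.222). Of 9965 tested genes placed in that order, 38 (0.381%) had at least as many fallen neighbours. Genes beside the same fallen genes each count, so these 38 are not independent and the share is not a test.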
